A study of Homo sapiens with 5 samples.

How the data were processed

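The series measured gene expression in TF-1 cells, an established human erythroleukaemia line that grows in the presence of GM-CSF and is used as a model of erythroid progenitors. Per the labels, cells carried either a GFP-marked empty retroviral vector or the same vector with a form of SCL that cannot bind DNA (called mutant SCL here). SCL is the basic helix-loop-helix factor encoded by TAL1. Cells were deprived of growth factor overnight and then stimulated for 6 h with GM-CSF at 5 ng/mL, with Steel factor (SF, the ligand of the receptor tyrosine kinase c-Kit) at 20 ng/mL, or with erythropoietin (Epo), whose dose the labels do not give. RNA was purified on silica columns and labelled with biotin by the array maker's protocol for small samples, per the labels' protocols, and was read on Affymetrix oligonucleotide arrays. The groups were vector cells under each of the 3 cytokines and mutant SCL cells under SF and under Epo. No group was left without cytokine, so a difference between cytokines cannot be assigned to either of them. Each of the 5 groups had 1 array, so no comparison had replicates and no p-value was computed. A model adding cell population and cytokine over 4 arrays would leave 1 residual degree of freedom, with any interaction as its error, and was not fitted.

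The deposited table holds 1 log2 signal per probe set and array, as summarised by the authors. No source used here states a normalization between arrays, and the method, its software and its versions are not given. That the unit is log2 was read from the deposited values, which run from 2.08 to 13.77, and 58.6% of the probe sets hold the same value on at least 2 arrays. The medians of the 5 columns were 4.99 for vector GM-CSF, 4.91 for vector SF, 4.90 for vector Epo, 4.96 for mutant SCL SF and 4.93 for mutant SCL Epo, a range of 0.08. Close medians would follow from a normalization between arrays, but the distributions were not equalised: the standard deviations ran from 1.79 to 1.91 and the 90th percentiles from 7.42 to 7.72. No centring of genes is visible. A summary that borrows information across arrays and a normalization between them, if either was used, can hide a shift common to most genes and can compress differences of weak probe sets.

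Values were used as deposited, because the column medians lay within 0.15 of each other, the tolerance set beforehand. Of the 22283 probe sets, 68 were array controls. Gene symbols came from the platform's annotation. It gave 1 symbol to 19071 probe sets, several to 1043 and none to 2107 others, and those without a single symbol were left out. Gene identifiers of 19059 probe sets were found in the current gene table, and 0 symbols needed updating. Where several probe sets shared a symbol, as for 4310 of the 11963 genes, the one with the highest mean over the 5 arrays stood for the gene, and disagreement with the others is given beside each named gene it concerns. Probe set signals of different genes were not compared with each other. The floor for low signals was the 40th percentile of all non-control values, a log2 signal of 4.45. Lower values were set to it, and a gene entered a comparison when at least 1 of the compared arrays was above it. On every array 7918 genes were above the floor.

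A gene was counted as higher or lower when its log2 difference was at least 1 (2-fold). Combined comparisons, SF against both other cytokines and mutant SCL under both cytokines, required this in the same direction in both differences. The spread between arrays was estimated without replicates, from the mutant SCL difference under SF minus that under Epo, halved and scaled by its median absolute deviation in 10 bins of expression. The spread of a single difference ran from 0.13 to 0.24 on the log2 scale. It includes any real interaction and leaves out any shift shared by many genes on an array. Being based on medians, it does not describe rare large deviations of single probe sets, and neither do simulations built on it. In 200 simulated sets of unchanged arrays with this spread, no comparison reached more than 1 counted gene. The counting rule was also tested on simulated data for mutant SCL against vector under SF, run on 11963 genes with 50 changed by each size. It counted 6% of 1.68-fold changes, 46% of 2-fold, 92% of 2.83-fold and 82% of 4-fold changes, and 0 unchanged genes. For mutant SCL under both cytokines the same shares were 0%, 16%, 92% and 78%. For arrays the number of arrays, here 1 per group, limits the precision.

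The 24 gene lists were written from general knowledge before the data were examined, as were the comparisons, the counting rule, the floor, and the alternatives, apart from those described below as chosen later. The lists hold 514 genes, of which 450 were on the array. For each list the median log2 difference was set against 10000 random lists of the same size matched on mean expression in 20 bins, and its percentile is given as a description of these arrays. The genes named were chosen by a rule fixed at the same time: per comparison the 10 highest and 10 lowest genes that were above the floor on all compared arrays and at least 2-fold different, up to 4 such members of each list, and TAL1, KIT, EPOR, CSF2RA and CSF2RB whatever their values. Another gene of the last group is not reported here. Other genes are named only where the text says that they were chosen after their values were seen.

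Where 2 comparisons shared an array, the correlation and covariance across genes were set beside those of simulated unchanged arrays. For overlaps of counted genes, the number given by independent lists was computed per direction. Array controls were used to describe the arrays: bacterial and phage spike-ins added at hybridization (9 probe sets), poly(A) spike-ins (12), 28S and 18S ribosomal RNA (3 each), and the 3' minus 5' signal of beta-actin and GAPDH. Alternatives were quantile normalization, centring on the median, floors at the 25th and 60th percentile, the mean of all probe sets of a gene, leaving out probe sets whose identifiers mark possible cross-hybridization where the gene has another, and a 1.5-fold rule. Chosen after seeing the data were a loess normalization with a span of 0.4, a comparison of arrays matched on hybridization controls, and residuals of the mutant SCL arrays from a line fitted to the 3 vector arrays on hybridization control or 28S signal. Matching set mutant SCL SF against vector GM-CSF and mutant SCL Epo against vector Epo. The first matched difference therefore also holds a change of cytokine, and the second is the same as in the main comparison. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures used matplotlib 3.10.9. No genome build was needed and no coordinates are given.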

Results

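Gene expression was profiled in TF-1 human erythroleukaemia cells on 5 arrays, 1 for each combination of vector and cytokine. Cells with the empty vector were stimulated for 6 h with GM-CSF, SF or Epo after overnight growth factor deprivation, and cells expressing mutant SCL were stimulated with SF or Epo. Signals of 11963 genes were compared, of which 8693 were above the floor on at least 1 array. Pairs of arrays correlated across the 7918 genes above the floor on all 5 arrays, with Pearson's r between 0.957 (vector GM-CSF with vector Epo) and 0.993 (vector SF with mutant SCL Epo). Genes are not independent replicates. There were no replicates, so each difference below is between single arrays, has no replicate check, and carries a spread of 0.13 to 0.24 log2 that was estimated without replicates.

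The arrays also differed in their controls. The 28S ribosomal RNA signal was 7.82 on the vector GM-CSF array, 6.55 on vector SF, 5.80 on vector Epo, 7.07 on mutant SCL SF and 6.69 on mutant SCL Epo. The 18S signal was 8.97, 8.38, 7.57, 8.31 and 8.23 in the same order. The hybridization controls, added in the same amount to each array by design of the assay, read 10.81, 10.29, 9.85, 10.82 and 10.04 in the same order. The poly(A) controls read 9.73, 9.87, 10.16, 9.89 and 10.15. The 3' minus 5' signal of beta-actin was 2.63, 1.89, 2.74, 3.33 and 3.01, being lowest on vector SF and highest on mutant SCL SF. A first principal component held 62.7% of the variance across genes and placed the vector GM-CSF array at one end (−0.68) and the vector Epo array at the other (0.60).

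**Figure D1:**
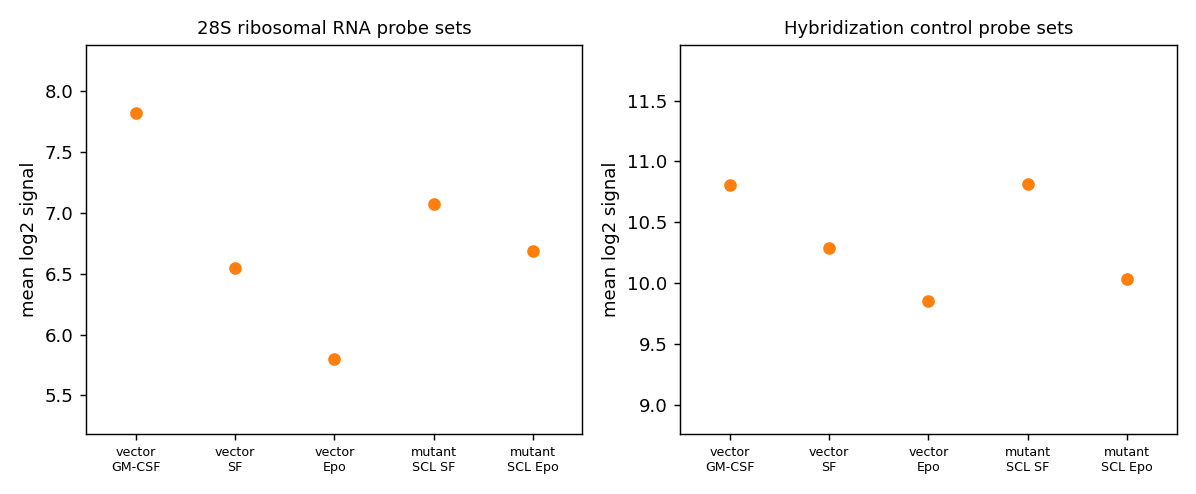
Mean log2 signal of the 3 probe sets for 28S ribosomal RNA (left) and of the 9 hybridization control probe sets (right) on each of the 5 arrays, 1 point per array. The vector GM-CSF array had the highest 28S signal (7.82) and the vector Epo array the lowest (5.80), and the hybridization controls of vector GM-CSF and mutant SCL SF (10.81 and 10.82) lay above those of the other 3 arrays.

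The genes of the factors under study came first. TAL1, which encodes SCL, had log2 signals of 7.57 in vector cells under GM-CSF, 8.31 under SF and 8.59 under Epo, and of 8.29 and 8.31 in mutant SCL cells under SF and Epo. In this probe set the mutant SCL arrays were thus not higher than the vector arrays of the same cytokine (differences of −0.02 and −0.29). A second TAL1 probe set above the floor lay between 7.49 and 7.75 on all 5 arrays, with differences of 0.06 and 0.19. Where these probe sets lie relative to the expressed construct was not determined here, so the TAL1 signal does not check the labels of the mutant arrays. KIT, the c-Kit receptor gene, had signals of 6.79, 7.04 and 7.02 in vector cells under GM-CSF, SF and Epo, and of 6.33 and 6.62 in mutant SCL cells under SF and Epo. Its mutant SCL difference was −0.70 under SF and −0.40 under Epo, short of 2-fold in both cases. EPOR, the Epo receptor gene, differed by 0.46 or less in every pair compared. For SF minus GM-CSF it gave −0.40, while 2 other probe sets above the floor gave 0.03 and 0.21. For SF minus Epo in mutant SCL cells it gave 0.46, and those 2 gave 0.00 and 0.10. CSF2RA, the alpha chain of the GM-CSF receptor, lay close to the floor on all arrays, between 4.60 and 4.82. CSF2RB, the common beta chain, was 7.25 under GM-CSF against 8.12 under SF and 8.36 under Epo in vector cells.

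The first comparison asked which genes differ under SF relative to GM-CSF, the factor in which the line is maintained. In vector cells 49 genes were 2-fold or more higher under SF and 2 were lower. The highest included CDK7, a kinase of the general transcription factor TFIIH (log2 difference 1.32), SRP9 of the signal recognition particle (1.27), the helicase gene DHX29 (1.20), ADNP (1.22), RCBTB1 (1.22) and MDN1 (1.20), which acts in ribosome assembly. RANBP2, a nuclear pore gene (1.34), and SNX4 (1.19) were higher too, although their other probe sets gave 0.32 to 0.42 and 0.57. EIF2AK2, the double-stranded RNA-activated kinase PKR, gave 1.40 and HIPK1 1.29 from 1 probe set each, while the other probe set gave −0.37 and −0.06. The 2 lower genes were TCF3 (−2.25, or 4.76-fold) and the ribosomal protein gene RPLP2 (−1.66). TCF3 encodes E proteins that pair with SCL, but the probe set was assigned to TCF3 by the platform's annotation alone, which was not checked, and 10 other TCF3 probe sets above the floor gave −0.80 to 0.03, and the other RPLP2 probe set gave −0.20.

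Among the gene lists, the DNA replication and G1/S genes were shifted upward under SF relative to GM-CSF, with a median difference of 0.38 that lay at the 99.69th percentile of matched random lists. None of its 26 compared members reached 2-fold, and 23 lay above 0. The mitosis and G2/M list had a median of 0.33 (98.22nd percentile), with 1 of 25 members counted, the spindle checkpoint gene MAD2L1 (1.06). The 10 compared stem and progenitor markers had a median of 0.31 (99.14th percentile) and no member at 2-fold. STAT5 target genes had a median of −0.13 (0.76th percentile), again with 0 of 15 at 2-fold. If lists held unrelated genes, 0.6 of the 24 would lie below the 2.5th percentile and as many at the same distance from the top, where 1 and 3 did. Genes of 1 list can move together for any cause, also one of the array. The 0.6 is therefore no chance number for these lists, and no excess is read from it. Of the integrin and adhesion genes 1 of 16 was counted, ITGA4 (1.17), and the list median of 0.18 lay at the 83.75th percentile. Of immediate early and feedback genes of the ERK pathway, which lies downstream of c-Kit, 0 of 17 were counted and the median was −0.06 (32.32nd percentile). Only 14 of the 22 members on the array were above the floor on all arrays. Without an array of unstimulated cells, this count does not measure signalling by c-Kit. The SF array had a 28S signal 1.28 below and hybridization controls 0.52 below those of the GM-CSF array. With the mean of all probe sets per gene, 23 genes were counted in place of 51, all higher under SF. Quantile normalization gave 37 higher and 5 lower, with 35 of the 51 kept. Loess, chosen after seeing the data, gave 35 higher and 4 lower, with 30 kept.

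The Epo array stood further from the GM-CSF array. In vector cells 297 genes were 2-fold or more higher under Epo than under GM-CSF and 10 were lower. CDK7 led with a log2 difference of 1.98 (3.95-fold), followed by EIF2AK2 (1.95, with −0.61 for its other probe set) and RTCA (1.82). PDSS1 of coenzyme Q synthesis (1.81), PHACTR2 (1.80, other probe sets −0.04 and 1.08) and the histone acetyltransferase gene HAT1 (1.75) came next. KLHDC2 (1.67), LIPT1 (1.66), the lysosomal membrane gene LAMP2 (1.66, other 1.24) and DUSP11 (1.65) completed the 10 highest. The 10 lower genes were TCF3 (−3.39), RPLP2 (−2.61), H3-3A (−1.33), SPN (−1.33), RMND5B (−1.30), EIF5A (−1.21), DOHH (−1.12), GAR1 (−1.07), RPL27A (−1.05) and TELO2 (−1.01). DOHH encodes an enzyme that modifies the EIF5A protein, and GAR1 a component of the particles that modify ribosomal RNA. Other probe sets gave smaller values for TCF3 (−0.63 to 0.00), RPLP2 (0.00), SPN (−0.63 to −0.07), RMND5B (−0.09), EIF5A (−0.99 and −0.09) and TELO2 (−0.59).

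Under Epo, genes of DNA replication and G1/S had a median of 0.58 at the 99.92nd percentile, with 22 of 26 members above 0. This is no second finding beside that under SF, since both use the vector GM-CSF array; across genes the 2 comparisons correlated with r of 0.908, where unchanged arrays sharing it give 0.499. MCM10 (1.34) and RFC4 (1.01) of this list were 2-fold or more higher. Of the mitosis list 3 of 25 were, MAD2L1 (1.27), the spindle motor gene KIF11 (1.22) and the cyclin gene CCNB1 (1.10), with the list median of 0.39 at the 94.38th percentile. The erythroid lists had counted members but medians near those of random lists. UROS (1.21) and ALAS1 (1.12), both of haem synthesis, were higher among 20 globin and haem genes, whose median was 0.05 (44.58th percentile). CA1, carbonic anhydrase 1 (1.01), was the 1 counted of 14 erythroid membrane and surface genes, whose median was −0.07 (17.08th percentile). In the list of the SCL complex and erythroid transcription factors, ID2, an inhibitor of basic helix-loop-helix factors, was higher (1.08, with 0.51 for its other probe set). TAL1 was also counted there (1.02), but its other probe set above the floor gave 0.02, and the median of the list was 0.04 (21.21st percentile). TAL1 and CA1 were each counted in only 3 of the 8 alternatives. Further counted list members were CSF2RB (1.11), the cell cycle inhibitor gene CDKN1B (1.20), the BCL2 family gene PMAIP1 (1.09), WDR12 (1.01), the chaperone gene HSPA5 (just at 2-fold), ITGA4 (1.31) and the scavenger receptor gene CD36 (1.20, other probe set 0.41). The medians of their lists lay between the 10.38th and the 92.09th percentile. Lymphoid markers, none of them counted, had a median of −0.24 (1.89th percentile) with 15 of 15 below 0. Of 20 on the array, only 12 were above the floor on all arrays. The median signal of this list was 4.83 against a floor of 4.45, so its shift is one of weak signals. The 28S signal was 2.02 lower and the hybridization controls 0.95 lower on the Epo array than on the GM-CSF array, and the median difference over genes ran from −0.10 in the lowest of 10 bins of expression to 0.30 in the highest. Quantile normalization left 202 counted genes, 176 higher and 26 lower, and the mean of all probe sets 195, of which 178 and 182 were among the 307. A loess normalization, chosen after seeing the data, gave 208 higher and 19 lower.

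Genes specific to c-Kit were sought as those that differed under SF from both other cytokines. Between SF and Epo in vector cells 125 genes differed at 1.5-fold, 29 higher and 96 lower under SF, and 3 at 2-fold. TCF3 was higher under SF (1.14, with −0.17 to 0.24 for its other probe sets), and PDSS1 (−1.17) and CSTB, the protease inhibitor cystatin B (−1.01), were lower. Among lists, genes of amino acid stress and the unfolded protein response had a median of −0.16 (0.29th percentile, 15 of 20 below 0, none at 2-fold). SCL complex and erythroid transcription factors had a median of 0.08 (99.67th percentile), ribosomal proteins 0.09 (99.78th) and lymphoid markers 0.07 (98.05th). The median signal of the lymphoid list lay close to the floor. No gene was 2-fold or more different in the same direction between SF and both GM-CSF and Epo. For 48.7% of 7918 genes the SF signal lay between those of GM-CSF and Epo, against 33.3% in simulated unchanged arrays. At 1.5-fold, 6 genes were higher under SF than under both, and they are named here after their values were seen. These were PLVAP, HNRNPU, USP24, PKM, MTA1 and PRKDC, with smaller differences of 0.60, 0.60, 0.61, 0.66, 0.74 and 0.97. PRKDC was below the floor under GM-CSF, and the other probe sets above the floor of HNRNPU and MTA1 gave −0.09 to 0.35 and −0.46 against GM-CSF.

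The second question was which genes differ with mutant SCL, from mutant SCL against vector cells under the same cytokine. Under SF, 29 genes were 2-fold or more lower with mutant SCL and 1 was higher. The beta-tubulin gene TUBB2A was lowest (−1.77, or 3.41-fold), followed by ID2 (−1.56, or 2.94-fold, with −0.67 for its other probe set). DENR, a translation factor gene (−1.36), CCDC47 (−1.34), the transporter gene SLC38A6 (−1.34) and the endothelial diaphragm gene PLVAP (−1.21) were also lower. For HIPK1 (−1.38), the aquaporin gene AQP3 (−1.27), the TFIIH gene GTF2H1 (−1.22) and MTA1 (−1.22), the other probe sets lay between −0.02 and 0.09. Of the globin and haem list HBD, delta globin, was lower (−1.04), and of the cholesterol synthesis list MSMO1 was (−1.09), each the 1 counted member of 20 and 13. The medians of these lists, 0.00 and −0.14, lay at the 62.45th and 10.20th percentile, and no list lay below the 2.5th percentile or as close to the top of the random lists. TCF3 was the gene that was higher (1.88), while its other probe sets gave −0.12 to 0.75. On the mutant SCL SF array the 3' minus 5' signal of beta-actin was 1.44 higher, the hybridization controls 0.53 higher and the 28S signal 0.53 higher than on the vector SF array. With the mean of all probe sets 18 genes were counted in place of 30.

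Under Epo, 23 genes were lower with mutant SCL and 8 were higher. CD36 (−1.53, or 2.90-fold, other probe set −0.36), ID2 (−1.49, or 2.82-fold, other probe set −0.75), CSTB (−1.43) and HEBP1, a haem-binding protein gene (−1.40), were the lowest. DUSP11 (−1.34), HMG20B (−1.33), PDSS1 (−1.30) and ARPC1A of the actin-nucleating Arp2/3 complex (−1.25) followed. The MHC class II gene HLA-DPA1 was lower in both of its probe sets above the floor (−1.29 and −1.58), and so was PTPRC, the leukocyte antigen CD45, to differing degrees in 3 (−1.22, −0.45 and −0.20). ALAS1 of the globin and haem list was lower by this rule too (−1.07), with the list median of −0.07 at the 14.49th percentile. The higher genes were GAR1 (1.55), SET (1.40, other probe set 0.68), the splicing factor gene SRSF1 (1.20, others −0.33 to 0.93), TCF3 (1.12, others −0.01 to 0.68), TELO2 (1.09, other 0.16), DOHH (1.07), the kinase gene PLK2 (1.01) and the zinc transporter gene SLC39A7 (1.01). Glycolysis and hypoxia genes had a median of −0.20 (1.02nd percentile, 16 of 22 below 0, none at 2-fold). Lymphoid markers, whose median signal lay close to the floor, had a median of 0.15 (99.65th percentile). Ribosome biogenesis and MYC target genes had a median of 0.05 (98.02nd percentile), which became −0.0010 with the mean of all probe sets. The 28S signal was 0.89 higher and the hybridization controls 0.18 higher on the mutant SCL Epo array than on vector Epo. With the mean of all probe sets 20 genes were counted in place of 31.

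The differences under SF and under Epo rest on separate arrays, which makes them the nearest thing to a repeat in this design. Of the 30 and 31 counted genes, 3 were shared in direction, 1 higher and 2 lower, where independent lists would share 0.001 and 0.08. ID2 was lower under both (−1.56 and −1.49), and its second probe set was lower under both as well (−0.67 and −0.75). PTPRC gave −1.17 and −1.22 in its brightest probe set, −1.22 and −0.45 in the second and −0.10 and −0.20 in the third. TCF3 was higher (1.88 and 1.12) in its brightest probe set, while the 10 others above the floor gave −0.12 to 0.75 under SF and −0.01 to 0.68 under Epo. Across 7918 genes the differences correlated with Pearson's r of 0.316 (0.0003 in simulated unchanged arrays), genes not being independent replicates. This correlation fell to 0.039 with arrays matched on hybridization controls, where mutant SCL SF was set against vector GM-CSF and so differed in cytokine too. It was −0.141 for residuals from the hybridization control line. Residuals from the 28S line gave 0.241 where simulated unchanged arrays give 0.243. All of these were chosen after seeing the data. At 1.5-fold, 46 genes were lower under both where independent lists would share 8.68, and 5 were higher where they would share 0.83. With the matched arrays, 1 gene was 1.5-fold lower and 5 were higher, and 1 of these 6 was among the 51 in the same direction. Both mutant SCL arrays had higher 28S signal than their vector arrays, while the 18S signal was 0.07 lower under SF and 0.66 higher under Epo. The mutant SCL arrays also had the largest 3' minus 5' signals, 3.33 and 3.01 for beta-actin against 1.89 to 2.74 on the vector arrays. For GAPDH these were 2.53 and 2.44 against 1.58 to 2.19. No alternative was built to correct for this. When the mutant arrays were set against a line through the 3 vector arrays on 28S signal, 1 gene, ID2, remained 2-fold away under both cytokines (−1.11 and −1.10). ID2 was not counted on the hybridization control line (−0.73 and −1.40) or with the matched arrays (−0.64 and −1.49), where PLK2 was the 1 gene counted. In the same order of 28S line, hybridization control line and matched arrays, PTPRC gave −0.67 and −0.55, −0.10 and −1.001, and −0.05 and −1.22. TCF3 gave 0.92 and −0.33, −0.29 and 0.61, and −0.38 and 1.12, so its shared direction was lost in all 3. With the mean of all probe sets 1 gene was counted in place of 3.

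**Figure D2:**
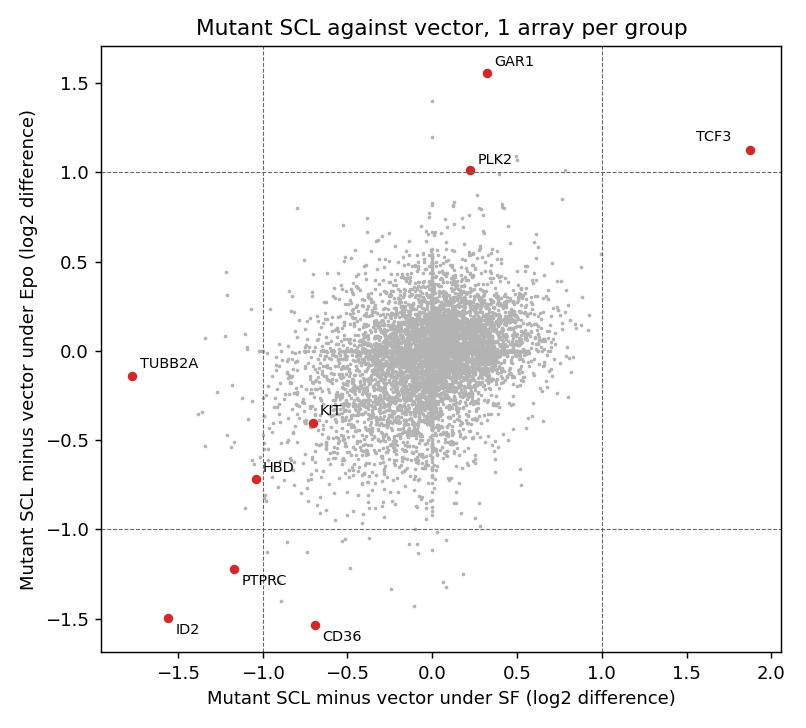
Log2 difference of mutant SCL minus vector under SF (x axis) and under Epo (y axis) for the genes above the floor on the 4 arrays, 1 grey point per gene, with 9 genes in red and dashed lines at 2-fold. ID2 (−1.56 and −1.49) and PTPRC (−1.17 and −1.22) lie beyond both lines at the lower left and TCF3 (1.88 and 1.12) at the upper right, while TUBB2A and CD36 pass 1 line each.

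**Figure D3:**
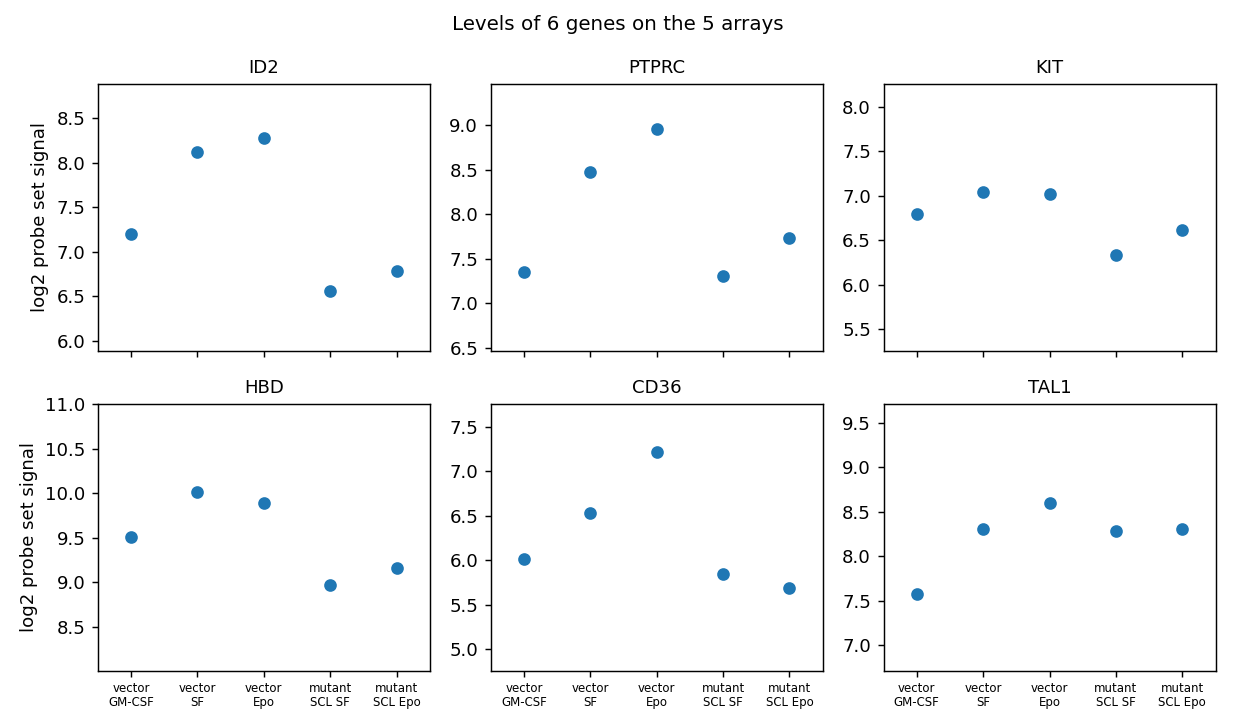
Log2 probe set signal of 6 genes on the 5 arrays, 1 point per array and no error bars since each group has 1 array. Each panel spans 3 log2 units around the gene's mean. ID2 is lower on both mutant SCL arrays (6.56 and 6.79) than on all 3 vector arrays (7.20 to 8.28), and TAL1 on the mutant SCL arrays (8.29 and 8.31) lies within the range of the vector arrays (7.57 to 8.59).

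Within mutant SCL cells, SF and Epo were further apart than within vector cells, with 17 genes lower under SF and 2 higher, although the difference between the cell populations was not tested. Lower under SF were GTF2H1 (−1.50, other probe set 0.40), KLHDC10 (−1.34, others 0.00), IFT25 (−1.27, other −0.27), DENR (−1.23), MSMO1 (−1.21) and AQP3 (−1.21, others −0.01 and 0.00). STIL (−1.18) and DBF4 (−1.06), which act in centriole duplication and the start of DNA replication, were lower as well, as were HMGN3 (−1.16) and CCDC47 (−1.07). XK was the 1 lower of 13 erythroid membrane and surface genes (−1.01), whose median was 0.13 (97.02nd percentile). FXYD5 (1.12) and TCF3 (1.89, others −0.55 to 0.52) were higher. BCL2 family and cell death genes had a median of −0.14 (1.67th percentile) and glycolysis and hypoxia genes one of 0.07 (98.00th percentile), with no member of either at 2-fold. Across genes, SF minus Epo in mutant SCL cells correlated weakly with SF minus Epo in vector cells (r of 0.098). The comparison shares the mutant SCL SF array with mutant SCL against vector under SF. GTF2H1, DENR, MSMO1, AQP3 and CCDC47 were counted as lower in both, which is no second finding for them. A second principal component, with 19.9% of the variance, set the mutant SCL SF array (−0.83) apart from the others (0.04 to 0.50). The hybridization controls were 0.78 higher on the mutant SCL SF array than on mutant SCL Epo. Quantile normalization left 12 counted genes and the mean of all probe sets 11, in place of 19.

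The last comparison set the genes that differed under SF against those that differed with mutant SCL. With no gene specific to SF at 2-fold there was no overlap to count. At 1.5-fold, 5 of the 6 genes higher under SF than under both other cytokines were at least 1.5-fold lower with mutant SCL under SF, HNRNPU (−0.24) being the exception. Both values use the vector SF array, so part of this may come from that array alone. Under Epo, without that array, the mutant SCL differences were −0.47 for PLVAP, 0.31 for HNRNPU, −0.01 for USP24, −0.32 for PKM, 0.44 for MTA1 and −0.01 for PRKDC, and 0 of the 6 were 1.5-fold lower. SF minus GM-CSF and mutant SCL minus vector under SF correlated with r of −0.587 across genes, with a covariance of −0.055, where unchanged arrays sharing vector SF give −0.50 and −0.018. The pair without a shared array, SF minus GM-CSF and mutant SCL minus vector under Epo, gave r of −0.462. In that pair 97 genes were at least 1.5-fold higher under SF and lower with mutant SCL, where independent lists would share 16.5. Epo minus GM-CSF and mutant SCL minus vector under SF, also without a shared array, gave r of −0.474 and 147 such genes where independent lists would share 42.1. The 28S signal differed in opposite directions in the 2 parts of both pairs (−1.28 and 0.89 in the first, −2.02 and 0.53 in the second), and the shares expected of independent lists do not account for it.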

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

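All tests in this part were chosen after the results they bear on had been seen.

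Control signals that no comparison used differed between the arrays. The 28S ribosomal RNA signal was 2.02 log2 higher on the vector GM-CSF array than on the vector Epo array, and the hybridization controls were 0.95 higher. The 3' minus 5' signal of beta-actin was 1.44 higher on the mutant SCL SF array than on the vector SF array.

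The pattern most affected is the 297 genes higher and 10 lower under Epo than under GM-CSF. The tables argue against a difference in hybridization controls as the whole cause. Scaled on the vector GM-CSF and Epo arrays, these controls predicted 0.97 for mutant SCL Epo minus mutant SCL SF, 2 arrays that did not select the genes, and the 297 genes had a median of 0.16 there (quartiles over genes 0.00 and 0.34). A larger share of ribosomal RNA in the labelled target of some arrays stays open, since 28S and 18S differed. Scaled on the vector GM-CSF and Epo arrays, the 28S signal predicted −0.31 for mutant SCL SF minus vector SF, where the median was −0.25. For mutant SCL Epo minus vector SF it predicted −0.08, and the median was −0.08. The 18S signal was 1.40 lower on vector Epo than on vector GM-CSF, while the genes were higher. On mutant SCL SF it was 0.07 lower than on vector SF, where the genes were lower too. It read 8.23 on mutant SCL Epo against 8.38 on vector SF. No prediction was scaled on 18S. A response to the cytokine stays open, since the genes were also higher under Epo than under SF in mutant SCL cells (median 0.16) while the 28S signal alone predicted 0.23. With 1 array per cytokine in each cell population, cytokine and array cannot be told apart for these genes.

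TCF3 was the gene with the largest difference under Epo against GM-CSF (−3.39), and it was also 2-fold apart in each of the other simple comparisons. A difference of this size was seen in 1 probe set only: over the 10 other TCF3 probe sets above the floor the median for Epo minus GM-CSF was −0.30. These ran from −0.63 to 0.00, so none reached 2-fold and none was higher under Epo. The platform's annotation assigns the brightest probe set to TCF3. That was not checked, so whether it measures TCF3 or another gene stays open, and a change in 1 form of the transcript stays open and was not tested.

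Genes lower with mutant SCL under both cytokines were the third pattern. For ID2 the array gradient in 28S signal is argued against, because both mutant SCL arrays stayed below the line of the vector arrays (−1.11 and −1.10, the smaller at −1.10) by several times the spread of a difference (0.20), and against hybridization controls the residuals were −0.73 and −1.40, or −0.64 and −1.49 with arrays matched on them. Against the vector array of the same cytokine, a signal of 1 probe set is argued against too, since the other ID2 probe set gave −0.67 under SF and −0.75 under Epo. Both ID2 probe sets are marked for possible cross-hybridization, so the alternative that leaves out such probe sets could not test ID2. The other ID2 probe set was not set against the control lines. On mutant SCL SF that other probe set read 5.86, against 5.95 on vector GM-CSF, the array matched on hybridization controls. For the correlation over all genes (0.316) the array gradient stays open: residuals from the 28S line correlated at 0.241, where simulated unchanged arrays give 0.243 through the shared line, but residuals from the hybridization control line correlated at −0.141, below the 0.018 simulated. That mutant SCL lowers ID2 is a hypothesis, and a difference between cell populations that were transduced separately, or in the 3' minus 5' signal of the arrays, stays open and was not tested.

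Some genes moved in opposite directions by 1.5-fold or more in the 2 parts of the design, on single arrays, and the difference between the parts was not tested. EWSR1 was lower with mutant SCL under SF (−0.80) and higher under Epo (0.80), a gap of −1.59, while its other probe set above the floor gave 0.07 and 0.11. For SF minus Epo, ARPC1A gave −0.81 in vector cells and 0.62 in mutant SCL cells, a gap of −1.43. HMG20B gave −0.82 and 0.59, a gap of −1.41. MTA1 gave 0.74 and −0.92, a gap of 1.66, while its other probe set gave 0.00 and 0.08. TUBB2A gave 0.60 and −1.03, a gap of 1.63.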

How the results depend on the processing

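The loess normalization, the matched arrays and the residuals from control lines were chosen after seeing the data; the other alternatives were set beforehand. Of 714 values of named genes under alternatives, 604 moved by less than the spread of a difference, 109 moved by more without changing sign, and 1 reversed: TAL1 under Epo against GM-CSF became −0.018 without the cross-hybridization-prone probe sets, where a probe set at the floor stood for the gene. Of 105 list medians 71 stayed within a factor of 1.5, 33 moved and 1 reversed, ribosome biogenesis and MYC targets under mutant SCL with Epo (−0.0010 with the mean of all probe sets). Part of the 604 values could not move by construction. A lower floor leaves genes above the main floor unchanged, and alternatives on probe sets leave genes with 1 probe set unchanged. The 1.5-fold rule, where included, changes no difference and no list median. The unmoved values are therefore not all checks, and those fixed in advance were not counted. The counts moved most with the 1.5-fold rule, by its construction: 700 for SF against GM-CSF, 125 for SF against Epo, 1344 for Epo against GM-CSF, 6 for SF against both, 431 and 290 for mutant SCL under SF and Epo, 51 for both, 314 for SF against Epo in mutant SCL cells, and 5 for the overlap of SF-specific and mutant SCL genes. The mean of all probe sets gave 23, 195, 18, 20, 1 and 11 for SF against GM-CSF, Epo against GM-CSF, mutant SCL under SF, under Epo and under both, and SF against Epo in mutant SCL cells. Quantile normalization gave 202 for Epo against GM-CSF and 12 for SF against Epo in mutant SCL cells. The cause was not tested. Quantile normalization also moved the share of higher genes under mutant SCL with Epo from 25.8% to 36.0%, under mutant SCL with SF from 3.3% to 10.7%, under SF against Epo in mutant SCL cells from 10.5% to 16.7%, and under SF against Epo in vector cells, with 3 and 2 genes, from 33.3% to 50%, as median centring and loess did too. With the mean of all probe sets none of those 2 genes was higher. For mutant SCL under both cytokines, arrays matched on hybridization controls counted 1 gene (PLK2, 1.22 and 1.01), as did residuals from the hybridization control line (PLK2, 1.08 and 1.02) and from the 28S line (ID2). The matched PLK2 value of 1.22 is mutant SCL SF minus vector GM-CSF. Against vector SF the PLK2 difference was 0.23. The correlation between the mutant SCL differences (0.316) became 0.039 with matched arrays and −0.141, reversed, with residuals from the hybridization control line. Each group has 1 array and the labels give no replicate numbers, so no fit with replicates as pairs was run and no array was left out; the 2 mutant SCL differences matched by cytokine are given side by side without a test. Signals near the floor limit what can be seen: 11963 genes were on the array and 7918 were above the floor on all 5 arrays.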

Other observations

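The gene lists and their comparisons were set beforehand. Which lists to give here was chosen after the values had been seen, as were the genes named and the count of separated genes.

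Several lineage and pathway lists had no member at 2-fold in any simple comparison. Under Epo against GM-CSF, interferon response genes had a median difference of −0.15 (18.57th percentile of matched random lists), inflammatory and NF-kB target genes −0.09 (17.57th), megakaryocyte markers −0.07 (37.16th), mast cell, basophil and eosinophil markers 0.00 (63.58th), granulocyte and monocyte markers −0.15 (24.09th) and heat shock genes 0.32 (74.03rd).

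Of 7918 genes, 371 were higher on both mutant SCL arrays than on all 3 vector arrays and 285 were lower. Exchangeable arrays without ties would give 791.8 each, so such an order alone does not set a gene apart. By the spread of a difference, 44 were separated as higher and 27 as lower. No chance value was computed for these counts. They therefore do not show that more genes were separated than unchanged arrays would give. Examples follow, named after their values were seen. MS4A4A had log2 signals of 7.03, 7.45 and 7.84 on the vector GM-CSF, SF and Epo arrays and of 8.33 and 8.32 on mutant SCL SF and Epo. Histidine decarboxylase, HDC, an enzyme of mast cells and basophils, had 6.04, 6.36 and 6.17 in vector cells and 6.82 and 6.77 in mutant SCL cells, while FCER1A of the same list went the other way (6.59, 7.18 and 7.28 against 6.37 and 6.53). PLK2 had 5.53, 6.52 and 6.44 in vector cells and 6.74 and 7.46 in mutant SCL cells. Genes lower on both mutant SCL arrays than on all vector arrays included HBD (9.51, 10.01 and 9.89 against 8.97 and 9.17) and the kinase gene LYN (9.36, 9.58 and 9.83 against 8.84 and 8.99). Their residuals from the 28S line were −0.76 and −0.64 for HBD and −0.67 and −0.61 for LYN. In each of the 2 other LYN probe sets at least 1 mutant SCL array was not below the vector GM-CSF array.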
